A study of Rattus norvegicus with 20 samples.

How the data were processed

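Liver RNA of 20 male rats was measured on 1-colour Affymetrix expression arrays, 1 array per rat. Per the labels' protocols, the rats received corn oil alone (control, n = 5) or tricresyl phosphate (TCP) in corn oil at 62.3, 124.5, 248.6, 497.3 or 994.6 mg/kg body weight (n = 3 each), and were dosed daily by gavage on 4 consecutive days. The labels assign separate rats to each group, so the spread between arrays includes the difference between animals. RNA came from pieces of the left liver lobe and was amplified with a biotin label, per the labels' protocols.

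The values the authors deposited are log2 expression values made with RMA, per the submitters' processing notes, with no version given in the sources used here. RMA corrects background, normalizes quantiles across arrays and summarizes the probes of a probe set, and which arrays were normalized together is not given in the sources used here. The values run from 2.74 to 15.4, and the array medians from 6.31 to 6.41. Because quantile normalization gives each array nearly the same distribution, a change is relative to the bulk of all genes. The number of arrays limits the precision, and no measure of signal over background was used here.

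The table held 31099 probe sets, of which 57 were controls. Of the other 31042, 20826 had 1 gene symbol in the annotation given, 436 had several and 9780 were unnamed here. Symbols were updated through the gene identifier for 20758 probe sets and through a transcript accession for 2, and the older symbol was kept for 66. A gene was represented by its probe set with the highest mean over all 20 arrays, which left 14217 genes, 4525 of them with more than 1 probe set. No filter on low values was applied, since a gene present only after treatment has a low mean.

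A linear model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes, default settings) in R 4.3.3, with 14 residual degrees of freedom and 4.77 prior degrees of freedom. Each dose was compared with control, neighbouring doses with each other, and all doses together with a moderated F test. A dose trend was the slope of the log2 value on dose step, from 0 for control to 5 for the highest dose. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. All p-values given for genes are limma's adjusted p, and errors of log2 changes are limma's standard errors. In simulated data with known changes, the comparison of 994.6 mg/kg with control recovered 72% of 50 genes changed by 0.5 on the log2 scale and 94% of those changed by 1, with 7 false calls among 14217 genes. The trend recovered 84% and 94%, with 9 false calls. The simulated noise was normal, independent between genes and equally wide in all arrays of a gene. It held no deviating array and no difference in RNA quality between groups, so these rates need not hold for the real comparisons.

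Fixed lists of genes, 34 in all, were written from general knowledge before the data were examined, and 603 of their 693 members were measured. They cover xenobiotic receptors, conjugation, esterases, lipid, bile acid, amino acid and glucose metabolism, stress and immune responses, and markers of the cell types a liver piece can hold. Some genes are in several lists, so the lists are not independent of each other. Each list was tested against the other genes with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's own genes move on balance one way. Adjusted p-values of lists are over the 34 lists. Counts of list members are given adjusted over all genes and adjusted over the list alone.

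Named genes were chosen by a rule fixed before the data were examined. It took up to 12 genes per direction with the largest called change at 994.6 mg/kg, and up to 5 at each lower dose, among genes whose 3 treated arrays all lay beyond the 5 control arrays, leaving out locus placeholders. It added up to 4 called members of each list, or the 2 with the largest change where none was called, up to 5 called genes per direction between the highest doses, and 12 genes named in advance, among them Cyp1a1, Bche and Pnpla6. The rule gave 107 genes. Not all of the genes named in advance were analysed here. Where other probe sets of a named gene moved the other way, none of them was called.

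Other settings were tried for the gene filter, the use of several probe sets, normalization, eBayes options, array weights, a replicate block (fitted without control replicates 4 and 5), fold thresholds, the arrays in the fit, the dose scale, the left-out array and the list test. Settings added after the data were seen were the counts of list members without replicate 1 of 994.6 mg/kg, the estimated correlation at lower doses, the difference between the 3' and 5' probe sets of the GAPDH control transcript as a covariate, and the same settings for named genes at the lower doses and between doses. That difference, from control probe sets on the array, grows when RNA is degraded or amplified less completely. Plots were drawn with matplotlib 3.10.9.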

Results

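Gene expression was measured in the livers of male Harlan Sprague Dawley rats after short repeated dosing with tricresyl phosphate, an organophosphate ester used as a plasticizer, flame retardant and lubricant additive. The 5 control rats received corn oil, and 3 rats received each of 62.3, 124.5, 248.6, 497.3 and 994.6 mg/kg. Log2 expression values of 14217 genes were compared. Correlations between arrays of a group ran from 0.986 to 0.996, and between arrays of different groups from 0.980 to 0.996. On the first principal component, with 20.1% of the variance, replicate 1 of 994.6 mg/kg lay at 37.1 and the other 19 arrays between -14.1 and 9.14.

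**Figure D1:**
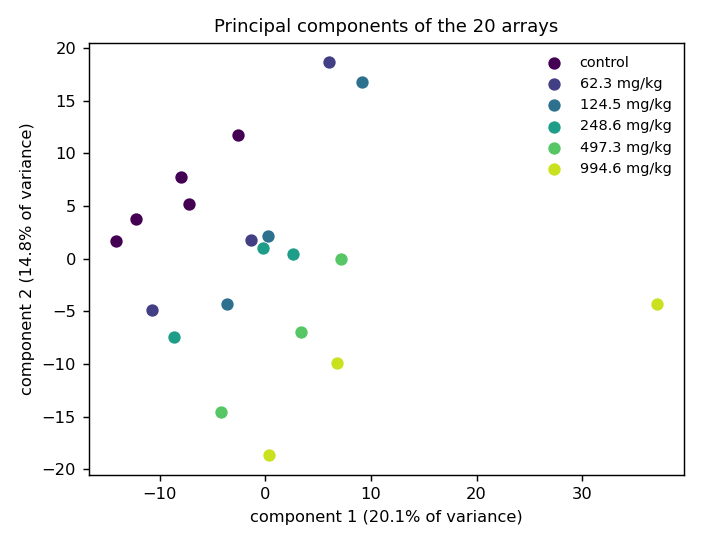
Each point is 1 array, coloured by dose, placed by its first component (20.1% of the variance) and second component (14.8%). Replicate 1 of 994.6 mg/kg lies at 37.1 on the first component, and the other arrays lie between -14.1 and 9.14.

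The 3' to 5' difference of the beta-actin and GAPDH control transcripts was on average larger in control than in treated arrays, and only that of beta-actin passed the test. For GAPDH it was 1.37 ± 0.18 on the log2 scale in control (SD, n = 5) and 0.72 ± 0.11 at 994.6 mg/kg (SD, n = 3), with 1 array of 124.5 mg/kg at 2.58. Control exceeded all treated arrays together by 0.40 for GAPDH (exact two-sided permutation p = 0.0719, adjusted over both transcripts 0.0719) and by 0.43 for beta-actin (exact two-sided permutation p = 0.0168, adjusted 0.0335). For GAPDH the control arrays lay at 1.13 to 1.56. Every treated array except that at 2.58 lay at 0.612 to 1.11, below all controls. In comparisons with control, this difference and the dose cannot be fully told apart.

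**Figure D2:**
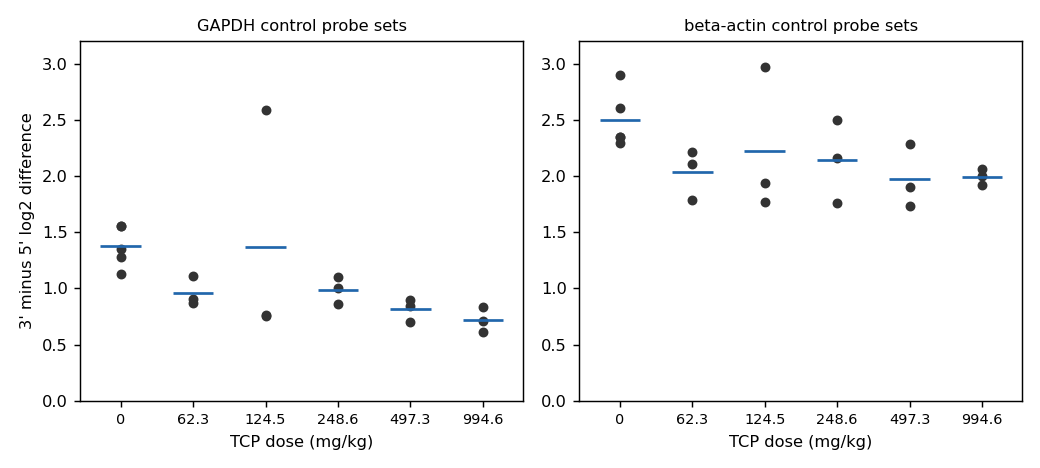
The vertical axis gives the log2 difference between the 3' and 5' control probe sets of GAPDH (left) and beta-actin (right), and the horizontal axis the dose, with 0 for control. Points are arrays and bars are group means, which for GAPDH are 1.37 in control, 1.37 at 124.5 mg/kg with 1 array at 2.58, and 0.72 at 994.6 mg/kg.

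The comparison of 994.6 mg/kg with control asked which liver transcripts changed at the highest dose. Ces2c, a carboxylesterase, rose by 2.92 ± 0.17 on the log2 scale (7.57-fold, adjusted p = 7.33e-09), and Abcc3, an export pump for conjugated drugs and bile acids, by 2.86 ± 0.24 (7.27-fold, adjusted p = 2.15e-06). Slc6a6, the taurine transporter, fell by 2.25 ± 0.13 (adjusted p = 5.16e-09), and Abcg5 and Abcg8, which together form the hepatic sterol export pump, fell by 2.34 ± 0.32 and 1.99 ± 0.23. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.23 ± 0.32 (adjusted p = 0.000474). Each of these genes lay beyond all 5 control arrays in all 3 treated arrays, as the rule that chose them required.

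Other large increases were Snx10 (2.84 ± 0.44), the clock repressor Nr1d1 (2.32 ± 0.35), the histamine-forming enzyme Hdc (2.16 ± 0.51), the stress gene Ddit4 (1.89 ± 0.38), the transcription factors Jun (1.88 ± 0.23) and Atf3 (1.76 ± 0.24), Wfdc21 (1.79 ± 0.42), Gsta3 (1.72 ± 0.20) and Usp18 (1.64 ± 0.29). Other large decreases were the cell cycle inhibitor Cdkn1a (-1.91 ± 0.43), Dhrs7l1 (-1.71 ± 0.47), the sulfate transporter Slc13a4 (-1.68 ± 0.25), the erythroid heme enzyme Alas2 (-1.63 ± 0.23), Mme (-1.58 ± 0.28), Stac3 (-1.58 ± 0.35), the globins Hbb (-1.54 ± 0.25) and Hba-a3 (-1.51 ± 0.24), and Tent5c (-1.47 ± 0.28). Without replicate 1, Ddit4 (adjusted p = 0.052), Wfdc21 (1.12), Dhrs7l1, Stac3 and Tent5c were not called, and Hbb was called at -1.001. With the GAPDH difference as a covariate, Hdc, Wfdc21, Cdkn1a, Dhrs7l1 and Stac3 were not called. The call of Hdc also ended without control replicate 1 or without replicate 2 or 3 of the dose, those of Cdkn1a (adjusted p = 0.0518) and Stac3 without replicate 3, and that of Dhrs7l1 without replicate 3 or control replicate 1, 2, 3 or 4. With the mean of its probe sets Cdkn1a changed by -1.09 (adjusted p = 0.0656).

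In all, 635 genes were called at 994.6 mg/kg, 356 higher and 279 lower, of which 274 changed at least 1.5-fold and 93 at least 2-fold. The larger direction depended on the setting: quantile normalization gave 984 genes, 471 higher and 513 lower, and leaving out replicate 2 of the dose gave 295 higher and 304 lower. With array weights 2841 genes were called, 1513 higher and 1328 lower. Without replicate 1 of this dose 173 genes were called, 158 of them shared, and the 477 others called with it kept their direction at an unadjusted p under 0.05. The remaining arrays had helped to choose these 477 genes, so this is no independent support for them. Without control replicate 1 the count was 378, and without control replicate 5 it was 411. With the GAPDH covariate 450 genes were called, 346 higher and 104 lower, and 332 of the 635 remained. All 635 kept their sign. The effect of the covariate is estimated within groups, where the GAPDH SD was 1.05 at 124.5 mg/kg and 0.098 to 0.18 elsewhere. It thus rests largely on 1 array of 124.5 mg/kg, at 2.58. Calls kept or ended with the covariate therefore do not separate dose from RNA quality. Of the 81 named genes called at this dose, the call ended for 39 without replicate 1, for 28 with the replicate block and for 26 with the covariate. It ended for 13 with only these groups fitted, for 1 with quantile normalization, for 5 with the mean of a gene's probe sets and for 4 with trend and robust eBayes settings. Whichever array of control or of the dose was left out, 36 kept their call.

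**Figure D3:**
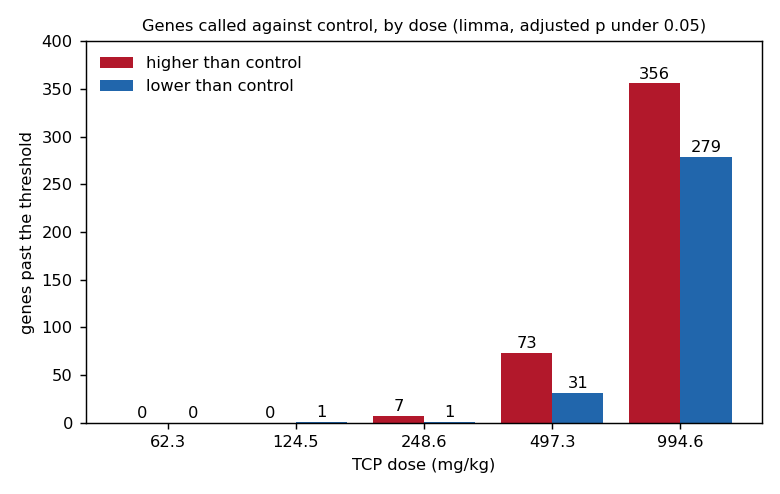
Bars give the number of genes past an adjusted p of 0.05 (vertical axis) at each dose in mg/kg (horizontal axis), red for higher and blue for lower than control. The count reached 104 at 497.3 mg/kg and 635 at 994.6 mg/kg.

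Targets of the xenobiotic receptors CAR and PXR rose as a list (camera adjusted p = 1.52e-11, and adjusted p = 0.00027 with an estimated correlation). Of 20 measured members 8 rose and 1 fell, and adjusted over the list alone 11 rose and 1 fell. Besides Ces2c and Abcc3, Ugt2b1 rose by 1.25 ± 0.14, Alas1, the first enzyme of hepatic heme synthesis, by 0.95 ± 0.18, and Ephx1, microsomal epoxide hydrolase, by 0.89 ± 0.11. The call of Alas1 ended with the replicate block (adjusted p = 0.0567). Cyp3a23-3a1, a drug-metabolizing cytochrome P450, rose by 0.90 ± 0.18 (adjusted p = 0.00716, and 0.058 without replicate 1 or 0.0506 with only these groups fitted). This was the only list called at 994.6 mg/kg with an estimated correlation.

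Glutathione transferases rose as a list (camera adjusted p = 0.00156, adjusted p = 0.13 with an estimated correlation), with 4 of 19 members higher and 6 adjusted over the list alone. Gsta3 rose by 1.72 ± 0.20 and Gstt3 by 1.14 ± 0.18, and Gsta4 (0.53 ± 0.11) and Gstt1 (0.42 ± 0.11) were not called without replicate 1. The call of Gstt1 also ended without replicate 2 or control replicate 1, 2, 3 or 4. NRF2 targets, the oxidative stress response, rose as a list (camera adjusted p = 0.000444, adjusted p = 0.13 with an estimated correlation), with 3 of 24 members higher and 1 lower, and 8 higher and 1 lower adjusted over the list alone. The members called higher over all genes were Nqo1, a quinone reductase (1.21 ± 0.22), Ephx1 and Gsta4. Each of them is also in another list: Nqo1 among AhR targets, Ephx1 among CAR and PXR targets and Gsta4 among glutathione transferases. Gclc, which makes the first step of glutathione synthesis, fell by 0.73 ± 0.16. It was not called without replicate 1, with the covariate or with the mean of its probe sets.

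Esterases are named targets of organophosphates, and as a list their transcripts were not called (camera adjusted p = 0.0763). The arrays measure transcripts only, so these values do not tell whether the enzymes themselves were inhibited. On ranks the list was called (camera adjusted p = 0.0215). Of 24 members 2 rose and 2 fell, and adjusted over the list alone 2 rose and 4 fell. Ces2c and the cholesteryl ester hydrolase Nceh1 (1.30 ± 0.28) rose, and hepatic lipase Lipc (-0.45 ± 0.09) and Aadac (-0.52 ± 0.13) fell. The calls of Nceh1, Lipc and Aadac ended without replicate 1, and that of Aadac also without control replicate 1, 3 or 5 and with the covariate. Bche, butyrylcholinesterase, differed by -0.07 ± 0.12 (adjusted p = 0.837), Pnpla6, neuropathy target esterase, by -0.17 ± 0.08 (adjusted p = 0.229) and Ces1d by -0.41 ± 0.13 (adjusted p = 0.0656). Both were called with array weights (adjusted p = 0.00715 and 0.00289), and Ces1d also with median centring (adjusted p = 0.0416) and without the lowest 50% of genes (adjusted p = 0.0448).

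Among 20 genes of bile acid synthesis and bile transport, 2 rose and 3 fell, with 3 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.439). Cyp8b1, the sterol 12-hydroxylase, rose by 0.69 ± 0.17 beside Cyp7a1, and Abcg5 and Abcg8 fell. The call of Cyp8b1 ended without replicate 2 (0.47, adjusted p = 0.142) or 3 (adjusted p = 0.0716), without control replicate 1, 2 or 3, and with only these groups fitted. Fatty acid and triglyceride synthesis was lower as a list (camera adjusted p = 0.0153, adjusted p = 0.406 with an estimated correlation and 0.0779 with fry), with 3 of 24 members lower and 1 higher, and 8 lower and 2 higher adjusted over the list alone. Dgat2, the last step of triglyceride synthesis, fell by 0.53 ± 0.10, Agpat2 by 0.43 ± 0.10 and Elovl5 by 0.42 ± 0.10, while Acaca, acetyl-CoA carboxylase, rose by 0.72 ± 0.20. Of these 4 only the call of Dgat2 held without replicate 1. That of Acaca also ended without any 1 of the 5 control arrays, that of Agpat2 without control replicate 1, 4 or 5 and with the covariate, and that of Elovl5 with the mean of its probe sets and with only these groups fitted.

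**Figure D4:**
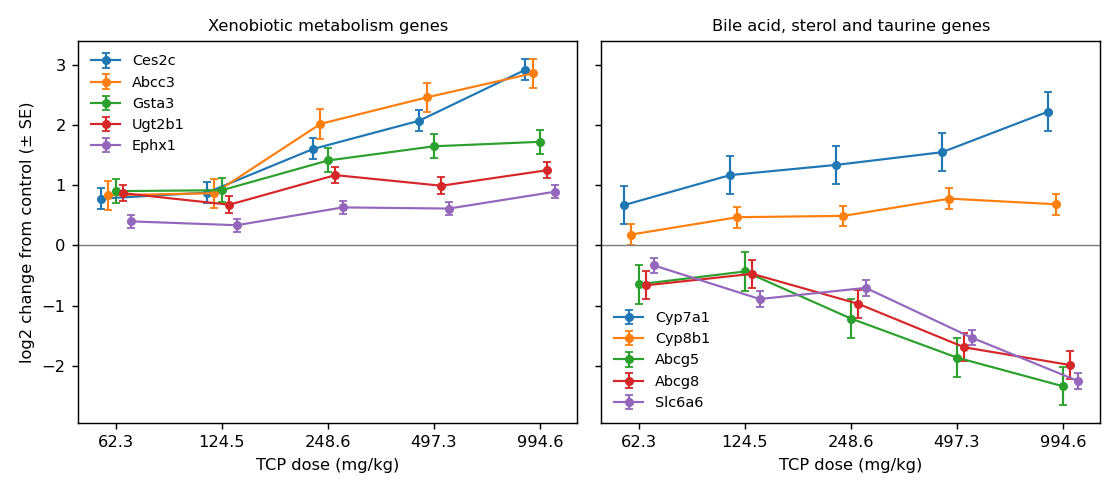
Points give the log2 change from control (vertical axis) with its SE at each dose in mg/kg (horizontal axis, doses spaced evenly and genes offset sideways), for genes of xenobiotic metabolism (left) and of bile acid, sterol and taurine handling (right). At 994.6 mg/kg Ces2c reached 2.92 and Abcg5 -2.34.

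The interferon response list rose (camera adjusted p = 6.71e-12, adjusted p = 0.13 with an estimated correlation). Of 22 members 9 rose and none fell, and 17 rose adjusted over the list alone. Usp18 rose by 1.64 ± 0.29, and the antiviral genes Mx1, Oas1a and Isg15 by 1.46 ± 0.31, 1.39 ± 0.34 and 1.35 ± 0.25. Without replicate 1 only 4 members were called, and Mx1 (adjusted p = 0.069) and Oas1a were not. The call of Oas1a also ended without replicate 3 or control replicate 2 or 5 and with the covariate. Proteasome subunits rose as a list (camera adjusted p = 7.38e-13, adjusted p = 0.13 with an estimated correlation), with 10 of 24 members higher and 17 adjusted over the list alone. The changes were small, as in Psma1 (0.59 ± 0.13) and Psmb3 (0.56 ± 0.11), and 0 subunits were called without replicate 1 (9 adjusted over the list alone, all higher) and 2 with the GAPDH covariate.

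Genes of the unfolded protein and integrated stress response rose as a list (camera adjusted p = 3.44e-07, adjusted p = 0.13 with an estimated correlation), with 7 of 24 members higher and 11 adjusted over the list alone. Ddit4 and Atf3 led, followed by Trib3 (1.40 ± 0.34) and the chaperone Dnajb9 (0.99 ± 0.27), and without replicate 1 only 2 members were called. The calls of Trib3 and Dnajb9 ended there, without control replicate 1 or 5 and with the covariate, and that of Dnajb9 also without control replicate 2 or replicate 2 of the dose. Acute phase and inflammation genes rose as a list (camera adjusted p = 3.11e-05, adjusted p = 0.227 with an estimated correlation), with 3 of 24 higher, and 10 higher and 1 lower adjusted over the list alone. The plasma proteins Orm1 (1.17 ± 0.16), Crp (0.82 ± 0.19) and Cp (0.25 ± 0.06) rose, and Crp and Cp were not called without replicate 1. The call of Crp also ended with the covariate (0.48), and that of Cp without control replicate 1, 3 or 5, with the mean of its probe sets (0.11) and with only these groups fitted.

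Urea cycle and amino acid breakdown was lower as a list (camera adjusted p = 0.000929, adjusted p = 0.169 with an estimated correlation). Of 24 members 5 fell and none rose, and adjusted over the list alone 9 fell and 1 rose. Histidine ammonia-lyase Hal fell by 0.83 ± 0.18, proline dehydrogenase Prodh by 0.72 ± 0.13, Hgd of tyrosine breakdown by 0.50 ± 0.09 and Nags, which makes the activator of the urea cycle, by 0.46 ± 0.13. The calls of Hal and Nags ended without replicate 1 and with the covariate, and that of Nags without any 1 of the 8 arrays of control and the dose. With the mean of its probe sets Prodh fell by 0.37.

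Red blood cell markers fell as a list (camera adjusted p = 3.46e-06, adjusted p = 0.0607 with an estimated correlation), with 3 of 6 members lower and 4 adjusted over the list alone. Hbb and Alas2 are given above, and the hemoglobin chaperone Ahsp fell by 0.53 ± 0.11, a call that ended without replicate 1 and with the covariate (-0.33). In replicate 1 the list mean lay 1.16 below the control mean, at -1.16, against -0.52 to 0.07 in the other 19 arrays. Without that array the list was called with an estimated correlation as well (adjusted p = 0.00208), with 2 members called.

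Among 17 circadian clock genes 3 rose and 2 fell, with 3 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.837). The clock repressors Nr1d1 and Nr1d2 rose by 2.32 ± 0.35 and 1.40 ± 0.14 and the clock output factor Dbp by 1.38 ± 0.25 (0.88 without replicate 3, also called), while Cry1 fell by 1.02 ± 0.19. Without replicate 1, 3 clock genes rose and 4 fell. Among 14 p53 targets 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.28). Gadd45a (1.45 ± 0.23), the death receptor Fas (0.69 ± 0.14) and Mdm2 (0.37 ± 0.10) rose and Cdkn1a fell, and Fas was not called without replicate 1 and rose by 0.41 with the mean of its probe sets. The call of Mdm2 ended without replicate 2 (adjusted p = 0.123) or 3 (adjusted p = 0.135), without any 1 of the 5 control arrays, with quantile normalization (adjusted p = 0.0715) and with only these groups fitted. That of Cdkn1a ended without replicate 3 and in the other fits given above.

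**Figure D5:**
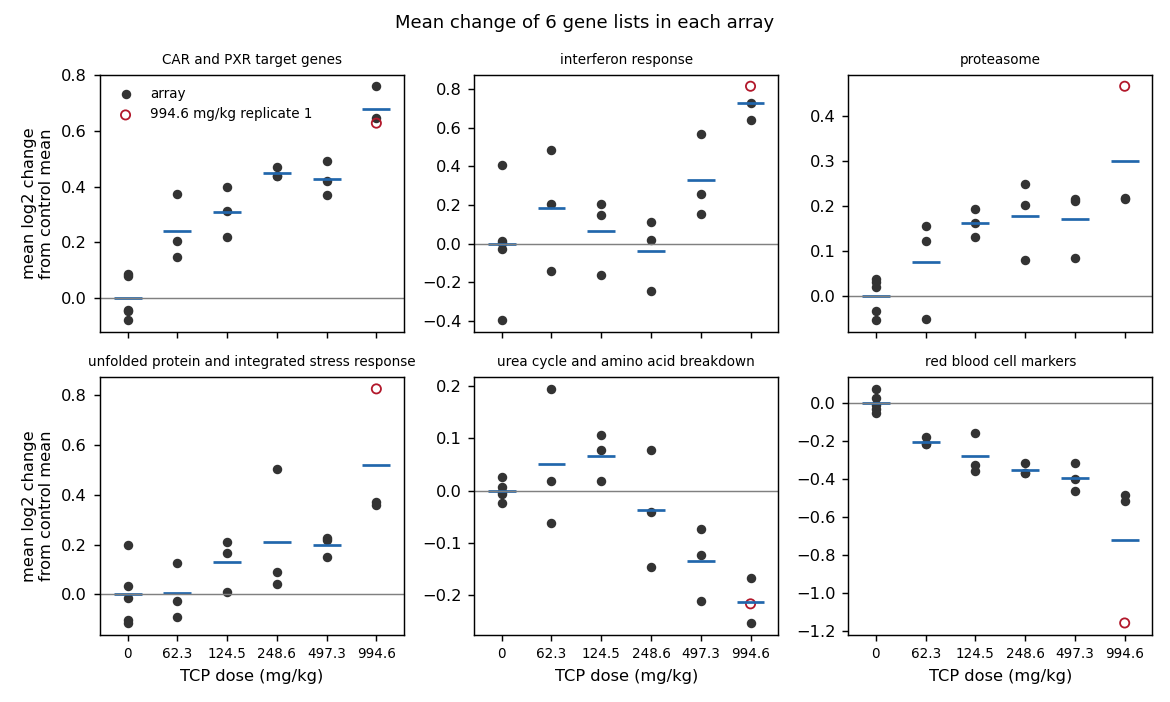
Each point is the mean log2 change of a list's members in 1 array from the control mean (vertical axis, a separate scale per list) by dose in mg/kg (horizontal axis, 0 for control), and bars are group means. The open red circle is replicate 1 of 994.6 mg/kg, which lies at -1.16 for red blood cell markers.

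The other metabolic lists were not called at 994.6 mg/kg. PPAR-alpha targets (camera adjusted p = 0.28) had 3 of 32 members higher and 2 lower, and 5 higher and 10 lower adjusted over the list alone, with Cyp4a8 (2.83-fold), Cd36 (0.92 ± 0.24) and Acot2 (0.67 ± 0.15) higher and Crat (-0.63 ± 0.17) and Cyp4a1 (-0.43 ± 0.12) lower. None of these calls held whichever array was left out. That of Acot2 ended without replicate 2 (0.57, adjusted p = 0.0675) or 3 (adjusted p = 0.0517) and with only these groups fitted (adjusted p = 0.0502). Those of the other 4 ended without replicate 1, without control replicate 1 or 2 and with the GAPDH covariate. They also ended without control replicate 3 for Cyp4a8, Crat and Cyp4a1, replicate 4 for Cd36 and Crat and replicate 5 for all 4, and without replicate 2 of the dose for Cyp4a1. Without replicate 1 Crat changed by -0.27 and Cyp4a1 by -0.28. AhR targets (camera adjusted p = 0.28) had 1 of 9 higher, also adjusted over the list alone, which was Nqo1, and Cyp1a1 differed by 0.91 ± 0.54 (adjusted p = 0.40). Glucuronosyl- and sulfotransferases (camera adjusted p = 0.0745) had 2 of 15 higher, also adjusted over the list alone, Ugt2b1 and Ugt2a1 (0.69 ± 0.13), and the list was called without replicate 1 (camera adjusted p = 0.0256) or control replicate 2 (camera adjusted p = 0.0347) and with fry (adjusted p = 0.00653). Glucose metabolism (camera adjusted p = 0.934) had 2 of 17 higher and 1 lower, and 2 higher and 2 lower adjusted over the list alone, with Gys2 (0.77 ± 0.15) and Fbp1 (0.32 ± 0.07) higher and Pc (-0.38 ± 0.10) lower, none of them called without replicate 1, where Pc changed by -0.22. The calls of Fbp1 and Pc also ended with the covariate, that of Fbp1 without replicate 2 and that of Pc without control replicate 1, 2, 3 or 5. Heme and iron metabolism (camera adjusted p = 0.934) had Alas1 higher and Tfrc (-0.84 ± 0.20) lower among 18 genes, and 4 higher and 5 lower adjusted over the list alone, and Tfrc was not called without replicate 1 or 2, with the covariate or with the mean of its probe sets. Lysosome genes (camera adjusted p = 0.572) had 1 of 20 higher, Ctsl (0.38 ± 0.07), and 3 higher and 2 lower adjusted over the list alone.

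Male-predominant liver genes (camera adjusted p = 0.0902) had 2 of 16 lower, Stac3 and Car3 (-0.87 ± 0.12), and 1 higher and 2 lower adjusted over the list alone. Female-predominant genes (camera adjusted p = 0.0651) had 1 of 14 higher, Abcc3, which is also in the CAR and PXR list, and 2 adjusted over the list alone. The male list was called without replicate 2 (camera adjusted p = 0.0472), and the female list without replicate 2 (0.042), without control replicate 5 (0.00622), with the mean of a gene's probe sets (0.015) and with fry (adjusted p = 0.00532). Cholesterol biosynthesis (camera adjusted p = 0.28), cell cycle (0.369), heat shock (0.269) and oxidative phosphorylation (0.0651) had 0 members called by limma, also adjusted over the list alone. Cholesterol biosynthesis was called without replicate 1 (camera adjusted p = 0.0325), and oxidative phosphorylation without control replicate 2 (0.0347) or 3 (0.0298) and on ranks (0.0239). Their largest differences were 0.49 ± 0.17 for Sqle, 0.51 ± 0.23 for Mcm4, 0.37 ± 0.16 for Bag3 and 0.37 ± 0.11 for Uqcrc2. Idi1 of cholesterol biosynthesis was called higher without replicate 2 (0.64, adjusted p = 0.0352) and Hspd1 of the heat shock list with array weights (0.16, adjusted p = 0.0416). Uqcrc2 was called with the mean of its probe sets (0.63, adjusted p = 0.0298), without the lowest 50% of genes (adjusted p = 0.0443), with quantile normalization (adjusted p = 0.0321), with trend and robust eBayes settings (adjusted p = 0.04997), with array weights (adjusted p = 0.0146) and without replicate 3 (adjusted p = 0.0378), and Sqle with array weights (adjusted p = 0.0293).

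Markers of other cell types were not called as lists apart from red blood cells, except that with the GAPDH covariate pancreas and gut markers were lower (camera adjusted p = 0.0284) and without replicate 1 cholangiocyte markers were called (camera adjusted p = 0.0355). With fry hepatocyte markers were called (adjusted p = 0.0155). Camera adjusted p was 0.28 for hepatocyte, Kupffer cell and endothelial markers, 0.934 for stellate cell, 0.322 for cholangiocyte, 0.742 for lymphocyte, 0.818 for neutrophil and 0.0792 for pancreas and gut markers. Rgs5 of the stellate list (0.82 ± 0.18) and Epcam of the cholangiocyte list (0.69 ± 0.14) rose and Cela1 of the pancreas list (-0.60 ± 0.12) fell, and Rgs5 and Cela1 were not called without replicate 1, nor Rgs5 with the covariate. The call of Epcam ended with the replicate block (adjusted p = 0.0646). Adjusted over the list alone, 1 hepatocyte marker was higher and 3 lower, 1 stellate cell marker higher and 1 lower, 1 cholangiocyte marker higher and 2 pancreas and gut markers lower. Without replicate 2 the endothelial marker Stab1 (-0.68, adjusted p = 0.0221) and the hepatocyte marker Apoa1 (-0.30, adjusted p = 0.0406) were called lower. Apoa1 was also called with trend and robust eBayes settings (adjusted p = 0.0445), and the hepatocyte marker Hnf4a was called lower with array weights (adjusted p = 0.00755). Median and mean differed in sign for PPAR-alpha targets, esterases, bile acid, glucose, stellate cell and lymphocyte lists, and for heme the test pointed down while median and mean lay above 0.

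At 497.3 mg/kg the largest increases were Ccl2, a monocyte chemokine (2.87 ± 0.48, adjusted p = 0.00736), Abcc3 (2.46 ± 0.24), Ces2c (2.07 ± 0.17), the interferon-induced chemokine Cxcl10 (1.65 ± 0.25) and Gsta3 (1.65 ± 0.20). The largest decreases were Scd, stearoyl-CoA desaturase (-2.45 ± 0.53, adjusted p = 0.0382), Abcg5 (-1.87 ± 0.32), Abcg8 (-1.70 ± 0.23), Slc6a6 (-1.53 ± 0.13) and the clock factor Bhlhe40 (-1.47 ± 0.28). Cyp7a1 rose by 1.55 ± 0.32 (adjusted p = 0.0258). CAR and PXR targets were again called (camera adjusted p = 3.08e-07, adjusted p = 0.00243 with an estimated correlation), with 5 of 20 members higher and 7 adjusted over the list alone. Of the lists, 8 were higher and 2 lower, and only CAR and PXR targets held with an estimated correlation. Glutathione transferases had 2 members higher and 7 adjusted over the list alone (camera adjusted p = 1.23e-05, adjusted p = 0.0705 with an estimated correlation). Proteasome subunits had 0 members called by limma over all genes and 6 higher adjusted over the list alone (camera adjusted p = 1.04e-05, adjusted p = 0.49 with an estimated correlation).

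In all 104 genes were called at 497.3 mg/kg, 73 higher and 31 lower, against 99 higher and 14 lower with the GAPDH covariate and 62 higher and 46 lower with median centring. The count moved with single arrays, to 62, 60, 65 and 54 without control replicates 1, 2, 4 and 5 and to 65, 38 and 53 without replicates 1, 2 and 3 of the dose. It was 235 when only these groups were fitted and 281 with array weights. The call of Scd ended without control replicate 1, 2, 3 or 5, without any 1 array of the dose and with the GAPDH covariate (adjusted p = 0.108). That of Cyp7a1 ended without control replicate 3 or 5 or replicate 2 or 3 of the dose, and the calls of both ended with trend and robust eBayes settings (adjusted p = 0.0843 and 0.062). That of Bhlhe40 ended without replicate 2 or 3 and with the covariate. That of Ccl2 ended without replicate 2 (adjusted p = 0.0567) and that of Abcg5 without replicate 3 (adjusted p = 0.0548).

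At 248.6 mg/kg 8 genes were called, 7 higher and 1 lower. Abcc3 rose by 2.02 ± 0.24 (4.06-fold, adjusted p = 0.000525), Ces2c by 1.60 ± 0.17 (3.04-fold), Gsta3 by 1.41 ± 0.20, Ugt2b1 by 1.17 ± 0.14, the aldehyde reductase Akr7a3 by 0.89 ± 0.16 and Ephx1 by 0.63 ± 0.11, and Slc6a6 fell by 0.71 ± 0.13. CAR and PXR targets rose as a list (camera adjusted p = 1.17e-11, adjusted p = 0.000202 with an estimated correlation), with 5 of 20 members higher and 8 adjusted over the list alone. Another 9 lists were higher and 3 lower, none with an estimated correlation, where glutathione transferases, NRF2 targets and red blood cell markers each had adjusted p = 0.0613. The count was 5 without control replicate 1, 3 or 5 or replicate 1 of the dose, 4 without control replicate 4, 3 without replicate 3 of the dose and 4 with the GAPDH covariate. It was 3 with only these groups fitted and 20 with array weights. The calls of Akr7a3, Ephx1 and Slc6a6 ended with the covariate, with median centring and with only these groups fitted, and those of Akr7a3 and Slc6a6 also with quantile normalization (adjusted p = 0.11 and 0.076) and with the mean of their probe sets. That of Akr7a3 also ended without any 1 control array or replicate 2 or 3 of the dose, that of Ephx1 without control replicate 2, 3 or 4 or any 1 array of the dose, and that of Slc6a6 without control replicate 1, 3, 4 or 5 or any 1 array of the dose. That of Gsta3 ended without replicate 3 (adjusted p = 0.0821) and with only these groups fitted (adjusted p = 0.0744). Abcc3, Ces2c and Ugt2b1 kept their call whichever array was left out.

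At 124.5 mg/kg Slc6a6 was the single gene called, lower by -0.89 ± 0.13 (adjusted p = 0.0172). It was not called without control replicate 1 or 4 or without replicate 2 or 3 of the dose, where limma called 0 genes. It was also not called with the mean of its probe sets or with array weights, where limma called 0 genes, or with only these groups fitted (adjusted p = 0.102), where Ces2c was the single gene called (0.88, adjusted p = 0.0089). Its change stayed negative in each of these fits. Without control replicate 5, Ugt2b1 (0.78, adjusted p = 0.0368) was called beside it. At 62.3 mg/kg limma called 0 genes, with 349 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0691 for Ugt2b1 (0.87 ± 0.14), which was called without control replicate 4 (adjusted p = 0.0469) or 5 (adjusted p = 0.0039) and without the lowest 50% of genes (adjusted p = 0.0489). CAR and PXR targets were higher as a list at both doses (camera adjusted p = 2.05e-08 and 1.04e-08, adjusted p = 0.00115 and 0.00096 with an estimated correlation), with 8 and 5 of 20 members higher adjusted over the list alone and 0 over all genes. Camera called 8 lists at 124.5 mg/kg and 12 at 62.3 mg/kg at the preset correlation, and this list alone with an estimated one. Red blood cell markers were lower at both (camera adjusted p = 0.000199 and 0.00108, adjusted p = 0.152 and 0.209 with an estimated correlation).

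Across all doses 920 genes had a trend, 554 rising and 366 falling, against 665 and 163 with the GAPDH covariate, 591 and 550 with median centring and 670 and 589 with quantile normalization. Ces2c rose by 0.55 ± 0.03 per dose step (adjusted p = 3.5e-10) and Abcc3 by 0.59 ± 0.04, and Slc6a6 changed by -0.41 ± 0.03 and Abcg5 by -0.46 ± 0.06. CAR and PXR targets had 8 of 20 members rising and 1 falling, with 11 and 1 adjusted over the list alone (camera adjusted p = 9.09e-10, adjusted p = 0.00187 with an estimated correlation). Proteasome subunits had 13 of 24 rising and 17 adjusted over the list alone (camera adjusted p = 4.22e-13, adjusted p = 0.105 with an estimated correlation). Red blood cell markers had 3 of 6 falling and 5 adjusted over the list alone (camera adjusted p = 3.8e-06, adjusted p = 0.0377 with an estimated correlation). Camera called 11 lists, 8 rising and 3 falling, and only CAR and PXR targets and red blood cell markers held with an estimated correlation. Without the control group 31 of the 920 genes were called. All 920 kept the sign of their slope, but the same treated arrays had helped to choose them. Without replicate 1 of 994.6 mg/kg 592 genes had a trend. The test of any dose called 116 genes, 74 without replicate 1 or without replicate 3 of 994.6 mg/kg, 77 without control replicate 1, 67 with the GAPDH covariate, 183 with quantile normalization and 1247 with array weights, which gave 2971 genes with a trend.

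Between the highest doses 3 genes differed. Jun was higher at 994.6 than at 497.3 mg/kg by 2.13 ± 0.25 (adjusted p = 0.00132) and Nr1d2 by 1.05 ± 0.16 (adjusted p = 0.0242), and the mitochondrial adenylate kinase Ak4 was lower by -0.83 ± 0.13 (adjusted p = 0.0275). Ccl2, called at 497.3 mg/kg and at 994.6 mg/kg only with array weights, differed by -1.92 ± 0.54 (adjusted p = 0.348) and Bhlhe40 by 1.75 ± 0.31 (adjusted p = 0.0618). Without replicate 1 of 497.3 mg/kg Ccl2 was called lower (-2.88, adjusted p = 0.000927). Bhlhe40 was called higher without replicate 2 of 994.6 mg/kg (adjusted p = 0.0121), with median centring (adjusted p = 0.0343), with array weights (adjusted p = 0.036) and without the lowest 50% of genes (adjusted p = 0.0443). The count was 15 without replicate 2 of 994.6 mg/kg (5 higher, 10 lower), 8 without replicate 1 of 497.3 mg/kg (2 higher, 6 lower), 6 without its replicate 2, 1 without replicate 3 of either dose and 122 with array weights (57 higher, 65 lower). The calls of Ak4 and Nr1d2 ended without replicate 1 or 3 of 994.6 mg/kg, without replicate 3 of 497.3 mg/kg, with the mean of their probe sets (-0.36 for Ak4) and with only these groups fitted, and that of Ak4 also without replicate 1 of 497.3 mg/kg. Interferon response genes were higher at 994.6 mg/kg as a list (camera adjusted p = 3.55e-07, adjusted p = 0.446 with an estimated correlation), and cell cycle genes were lower (camera adjusted p = 1.66e-07, adjusted p = 0.446 with an estimated correlation). Between 248.6 and 497.3 mg/kg Tnfaip3, an inhibitor of inflammatory signalling named here because it was the single gene called, was higher by 1.26 ± 0.19 (adjusted p = 0.0474). Its call ended without any 1 array of 248.6 mg/kg, without replicate 2 or 3 of 497.3 mg/kg, with the mean of its probe sets, with array weights and with only these groups fitted (adjusted p = 0.275). Without replicate 1 of 497.3 mg/kg, Ccl2 (3.62, adjusted p = 9.43e-05) and Cxcl10 (1.77, adjusted p = 0.015) were called higher in this comparison. The other neighbouring doses had 0 genes called by limma, with 299 at an unadjusted p under 0.05 between 62.3 and 124.5 mg/kg and 343 between 124.5 and 248.6 mg/kg.

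Of the genes called at 497.3 mg/kg, 65 were called in the same direction at 994.6 mg/kg, 46 higher and 19 lower, with Abcc3, Ces2c, Gsta3 and Cyp7a1 among the higher and Abcg5, Abcg8 and Slc6a6 among the lower. Independent lists of these sizes would share 1.83 higher and 0.608 lower genes. Unchanged groups simulated against the same controls shared 0 in each of 100 draws. Hardly any gene can be called in such groups, so this count does not tell what the shared controls add to the 65. With the controls split between the comparisons, 15 and 11 genes were shared. Each comparison then had fewer controls, which also lowers the number of calls, so these counts do not tell what the shared controls add either. Across genes, which are not independent replicates, the changes at both doses had a correlation of 0.635, against 0.376 simulated, and a covariance of 0.0328, against 0.00768 simulated, a difference of 0.0252. With the controls split, so that no control array was shared, the correlations were 0.471 and 0.488 and the covariances 0.0272 and 0.0284.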

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

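The tests of whether clock genes depended on a single array, of the hour of necropsy, of the array scale and of the amount of blood were chosen after their results were seen, as was the fit with the GAPDH covariate. The tests of the array that stood apart and of other splits of the arrays were fixed before their results were seen.

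Replicate 1 of 994.6 mg/kg lay at 37.1 on the first component, and leaving it out lowered the count of called genes from 635 to 173. Degraded RNA is argued against, since its GAPDH 3' to 5' difference of 0.612 was below that of every other array. Its red blood cell markers lay 3.53 SD beyond the other arrays, with 6 of 6 members lower, which meets the criterion set in advance for a different share of another cell type in that piece, and the next list, neutrophil markers, lay 0.849 SD beyond. Whether this accounts for the array's other genes was not tested. A larger response of that animal also stays open: over the 173 genes called without it, 96.0% moved in the direction of the call, with a median change of 0.792 against 0.754 in the other arrays, a ratio of 1.05. These genes were chosen by the other arrays of the dose against the same controls. That choice favours a shared direction and enlarges the change in those other arrays, so these values do not decide it.

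Clock genes changed at 994.6 mg/kg. A single array is argued against as the cause, since 7 clock genes were past the threshold without replicate 1, Nr1d1, Nr1d2 and Dbp higher and Bmal1, Npas2, Cry1 and Nfil3 lower. Another hour of the day at necropsy could give this pattern: 0 called genes opposed the others of their phase, while Per3 and Clock each lay above the control mean in 2 of 3 arrays. A shift of the clock by the treatment would give the same values, so both stay open and cannot be told apart, as necropsy times were not used here.

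Red blood cell transcripts were lower at 994.6 mg/kg, where Hbb, Hba-a3 and Alas2 were called. At 497.3 mg/kg the fit of all arrays did not call them (limma adjusted p = 0.286, 0.179 and 0.169), though each was called with only these groups fitted. At no lower dose was the list called with an estimated correlation. As a test of a shift of the array scale, median centring and quantile normalization changed the calls of 273 and 389 other genes at 994.6 mg/kg. They left Hbb, Hba-a3 and Alas2 called, with mean changes of -1.56 and -1.58 and each at least 5.76 SE below control. The median change of all genes was already -0.00713, so re-scaling could move these values only slightly and the outcome was fixed in advance. It shows only that no scale difference left in the deposited values accounts for them. Less blood in the treated pieces may be the cause: the mean changes of S100a8 and S100a9, transcripts of blood neutrophils, and of Hbb, Hba-a3 and Alas2 differed by 1.89 (2.50 SE) with all arrays, which argues against it, but by 0.701 (1.18 SE) without replicate 1. The requirement that both differences exceed 2 SE was set after the first was seen, so this explanation stays open too. A lower number of young red blood cells in the treated rats was not tested.

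Chance as the source of the split of the arrays is argued against for 994.6 mg/kg (635 genes, highest other split 4), 497.3 mg/kg (104, highest other 1) and 248.6 mg/kg (8, highest other 0). At each, 1 of 56 splits gave as many genes, the smallest share this test can give. The doses share the control arrays, and the shares were not adjusted over the doses. Chance is also argued against for the dose trend (920, highest other 4 of 100 assignments) and for any dose (116, highest other 36). It cannot be excluded for 124.5 mg/kg (1 gene, highest other 1, as many in 3 of 56 splits). At 62.3 mg/kg 0 genes were called (highest other 1), so 56 of 56 splits give as many whatever the data, and the splits decide nothing. Between 994.6 and 497.3 mg/kg the 10 splits are too few for a share under 0.05 (3 genes, highest other 0).

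Among 143 values of named genes and lists in the control group, 8 had 1 array far from the other 4, and chance gives about 1 in 20. The gap to the nearest array was 0.858 of the range for Ahsp, where replicate 2 was higher. It was 0.863 for Ak4 and 0.819 for Cela1, where replicate 4 was lower in both. It was 0.762 for C1qb, where replicate 2 was lower. It was 0.733 for Cxcl10, where replicate 5 was higher. It was 0.739 for Dhrs7l1 and 0.743 for Gadd45a, where replicate 5 was lower in both. It was 0.761 for the mean of the hepatocyte markers, where replicate 4 was higher.

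Of 10216 probe sets without a single gene here, 156 were called at 994.6 mg/kg, 60 higher and 96 lower. The largest called changes were as follows. Among those that rose, one changed by 2.59 ± 0.28 on the log2 scale (adjusted p = 5.49e-05) and another by 1.51 ± 0.26 (adjusted p = 0.00392). Among those that fell, one changed by -2.55 ± 0.36 (adjusted p = 0.000746) and the next by -2.05 ± 0.33 (adjusted p = 0.00191).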

How the results depend on the processing

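The GAPDH covariate, and the application of the settings to named genes below 994.6 mg/kg, were chosen after the data were seen, and the other settings given here before. No named gene called in a comparison changed sign there under the settings run for it, and no list called at 994.6 mg/kg was called in the other direction. The larger direction of the counts did turn at 994.6 mg/kg, from 356 higher and 279 lower to 471 and 513 with quantile normalization, 154 and 156 with the replicate block and 295 and 304 without replicate 2. At 497.3 mg/kg it turned from 73 higher and 31 lower to 18 and 20 with the replicate block, and at 248.6 mg/kg from 7 and 1 to 31 and 36 with an unadjusted p and at least a 1.5-fold change, which at 124.5 mg/kg gave 26 higher and 19 lower. Between the highest doses it turned from 2 higher and 1 lower to 57 and 65 with array weights, 2 and 6 without replicate 1 of 497.3 mg/kg and 5 and 10 without replicate 2 of 994.6 mg/kg. The single gene called at 124.5 mg/kg was Slc6a6, lower, but Ugt2b1, higher, with the replicate block and Ces2c, higher, with only these groups fitted. For the counts given here the cause was not tested, except where a setting uses fewer genes, fewer arrays or another threshold. Without the lowest 50% of genes, 1 gene was called at 62.3 mg/kg and 6 between 994.6 and 497.3 mg/kg, and 3 lists with under 2 members left were not tested. With the mean of a gene's probe sets, 0 genes were called at 124.5 mg/kg and 1 between the highest doses, and with each probe set on its own 6 between the highest doses. Quantile normalization gave 984 genes at 994.6 mg/kg and 183 at any dose, and ended the calls of Mdm2 at 994.6 mg/kg (adjusted p = 0.0715) and of Akr7a3 (adjusted p = 0.11) and Slc6a6 (adjusted p = 0.076) at 248.6 mg/kg. Median centring gave 6 genes between the highest doses, and eBayes with trend and robust settings 5. Array weights gave 0 genes at 124.5, 20 at 248.6, 281 at 497.3 and 2841 at 994.6 mg/kg, 2971 with a trend, 1247 at any dose and 122 between the highest doses. With these weights the changes of Car3, Cela1, Crat, Dhrs7l1, Elovl5, Hal, Hbb, Nqo1, Pc, Rgs5, Slc13a4, Tent5c and Trib3 at 994.6 mg/kg were over 1.5 times smaller and that of Cyp8b1 over 1.5 times larger, and all kept their call. Replicate number as a block was fitted without control replicates 4 and 5, and the effects of blocking and of fewer controls were not separated. With this block, 1 gene was called at 62.3, 38 at 497.3 and 310 at 994.6 mg/kg and 67 at any dose. The call ended for 28 of the 81 named genes at 994.6 mg/kg. The settings listed above for single genes mostly leave this block out. It also ended the calls of Cyp7a1 (adjusted p = 0.117), Bhlhe40 (0.075) and Ccl2 (0.0662) at 497.3 mg/kg, among others. At 248.6 mg/kg it ended those of Akr7a3 (adjusted p = 0.541) and Slc6a6 (0.657). Lists called only with this block were PPAR-alpha targets (camera adjusted p = 0.0287) and cell cycle (camera adjusted p = 0.0119). The block also called male-predominant (camera adjusted p = 0.0113) and female-predominant genes (camera adjusted p = 0.0102). Whether replicate numbers mark a shared source of variation stays open. Deviations from the group means had a correlation over 0.1 in 16 of 45 pairs of same-numbered arrays. Over all these pairs the correlations ran from -0.382 to 0.366. Of 18 arrays, 8 had their best match in another group under their own number. Some such matches arise by chance, and the correlations of differently numbered pairs are not given here, so these counts do not decide it.

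With an adjusted p and at least a 1.5-fold change, 61 genes were called at 497.3 and 274 at 994.6 mg/kg and 268 with a trend. With an unadjusted p and at least a 1.5-fold change the counts were 24, 45, 67, 240 and 403 from the lowest to the highest dose, 381 for the trend, 425 for any dose and 198 between the highest doses. With the GAPDH covariate, 4 genes were called at 248.6 mg/kg and 67 at any dose. With only the groups compared in the fit, 3 were called at 248.6 and 235 at 497.3 mg/kg. The trend without the control group had 31 genes. Camera with an estimated correlation called 1 list at 994.6 mg/kg. With the controls split, and so fewer controls in each comparison, 15 and 11 genes overlapped between the highest doses.

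Leaving out 1 replicate at a time gave 0 to 1 genes at 62.3, 0 to 2 at 124.5, 3 to 9 at 248.6, 38 to 73 at 497.3 and 173 to 684 at 994.6 mg/kg. It gave 592 to 1108 genes with a trend, 74 to 154 at any dose, 1 to 15 between the highest doses and 10 to 13 lists at 994.6 mg/kg. No measure of signal over background was used here, so what low signal limits is not known.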

Other observations

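The tests of immediate early, LXR and glucocorticoid target genes used lists written after the changes of Jun, Atf3, Abcg5, Abcg8 and Tsc22d3 were seen and before the lists' own results were seen. The genes that prompted each list were left out of it.

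Immediate early genes, which respond quickly to many stimuli, were tested as a group because Jun and Atf3 rose at 994.6 mg/kg. Of 16 other members limma called 0, and the group was not shifted (camera p = 0.0914, and p = 0.291 with an estimated correlation, adjusted over the 3 added lists 0.152 and 0.71). The largest values were 1.14 ± 0.40 for Dusp1 (adjusted p = 0.112) and -1.11 ± 0.47 for Egr1 (adjusted p = 0.199).

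Targets of LXR, a receptor for oxidized sterols, were tested because Abcg5 and Abcg8 fell. Of 11 other members 1 fell, Pltp, by 0.47 ± 0.12 on the log2 scale (limma adjusted p = 0.032). The group was not lower (direction up, camera p = 0.869 at the preset correlation and 0.871 with an estimated correlation, adjusted over the 3 added lists 0.869 and 0.871). Abca1, a cholesterol exporter, differed by 0.33 ± 0.25 (adjusted p = 0.528) and Scd by -1.59 ± 0.53 (adjusted p = 0.096). Scd was called lower with array weights (-1.37, adjusted p = 0.0115), with the replicate block (-2.16, adjusted p = 0.022) and without control replicate 4 (-1.97, adjusted p = 0.0302).

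Glucocorticoid targets were tested because Tsc22d3, chosen after its values were seen, fell by 1.07 ± 0.30 on the log2 scale (adjusted p = 0.0462). Of 15 other members 1 was higher, the metallothionein Mt2A, by 1.03 ± 0.29 (limma adjusted p = 0.047). The group was not lower (direction up, camera p = 0.102 at the preset correlation and 0.474 with an estimated correlation, adjusted over the 3 added lists 0.152 and 0.71). Fkbp5 differed by -0.36 ± 0.52 (adjusted p = 0.784).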
